A study of Mus musculus with 6 samples.

How the data were processed

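The series holds 6 single-cell RNA sequencing libraries of sorted EYFP positive and EYFP negative mouse pancreatic cells from 3 runs, runs 1 and 2 in homeostasis and run 3 after cerulein, per the labels. The deposited values are raw UMI counts per gene and cell barcode, which are integers per the file headers. Per the submitters' processing notes the authors used Cell Ranger 2.1.0 and the build GRCh38, while the file headers give a software version of 3.1.0 and all 31053 gene identifiers are those of the mouse, so the mouse build is not given in the sources used here. Barcodes had been called as cells before deposit. The deposited features held 0 rows for the EYFP transgene, so the sort could not be checked in the counts.

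Tests, gene lists, marker lists and most alternatives were chosen before the data were examined. Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. In EYFP negative runs 1, 2 and 3, 86, 421 and 2104 barcodes had fewer genes and 365, 570 and 39 had more mitochondrial UMIs, and in the EYFP positive runs 130, 27 and 209 and 94, 18 and 103. Scrublet, run per library in scanpy 1.11.5 with 20 components, called 2, 6 and 26 doublets in the EYFP negative and 3, 0 and 4 in the EYFP positive libraries, which were removed, leaving 4888 of 8582 barcodes. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9) gave 21 clusters, without correction between libraries. A cluster took the class of 15 fixed marker lists with most markers among its 10 leading genes and at least 3 detected markers, and all 21 were named. The 2 acinar-like clusters, 16 and 20, were pooled unless a text says otherwise. Classes in the text are these marker-based likenesses. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

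UMI counts were summed per library over the cells of a class and tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors were taken from the fitted log2 fold change and its F value. EYFP positive and negative libraries were compared over all 6 libraries with condition in the model, and pancreatitis, homeostasis and their interaction with EYFP in a model with 1 mean per group, in which the lone pancreatitis library was assumed to vary like the others. Other classes were tested with at least 10 cells in each library, the pancreatitis contrast in the 3 EYFP negative libraries only. The 17 gene lists were digestive enzymes, acinar transcription factors, secretory pathway and unfolded protein response, duct and acinar-to-ductal metaplasia, Reg family and acute-phase, proposed progenitor markers, cell cycle, dissociation and immediate-early, inflammatory cytokines and NF-kB targets, interferon response and antigen presentation, extracellular matrix and fibrosis, p53 targets and apoptosis, oxidative stress, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded and sex-linked genes. Each list with at least 3 measured genes was tested with camera of limma 3.58.1 (correlation 0.01, adjusted over lists), and again with an estimated correlation and with fry. Shares of classes and of cycling cells (at least 2 of 20 mitotic genes at 1000 UMIs per cell) were compared with a two-sided exact permutation test, whose smallest p is 0.1.

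Named genes followed a fixed rule. In each acinar-like EYFP and pancreatitis comparison up to 10 genes per direction with the largest change were eligible among those with an adjusted p under 0.05, a mean log2 CPM of at least 5 and 1 direction in every run. Where fewer than 5 passed, the 5 genes of lowest p per direction were given as values. Up to 4 members of lowest p per list and up to 5 genes per direction in other classes were added, with the EYFP transgene, Cpa1, Ptf1a, Krt19, Sox9, Reg3b, Spp1, Mki67, Xist, Ddx3y, Stmn1, Tert, Dclk1 and Bmi1 always eligible. Genes called only under an alternative are named as such. Where 1 group of libraries held 0 UMIs of a gene, a bound was computed with a floor of 3 counts over that group, and with 1 to 3 UMIs a ratio of summed CPM with a 95% counting interval.

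Alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0, no low-count filter, all deposited barcodes, stricter cells (at least 500 genes, at most 10% mitochondrial UMIs), doublets kept, resolution 0.5, library sizes without enzyme genes, sums thinned to the smallest library, each library left out, and run as a block. Cluster 16 alone, each cluster of another class left out in turn (where each library kept 10 cells), the fit of all 6 libraries in other classes, the ductal-like cells without 1 cell, DESeq2 and both cell filters in other classes, and leaving out libraries for shares and other classes were added after the data were seen. Whether run numbers pair libraries was checked, per the labels' run numbers, by correlating within-condition residuals of the EYFP positive and negative library of a run. The r was 0.405 in acinar-like, 0.311 in ductal-like, 0.278 in endothelial-like, 0.212 in B or plasma-like and 0.210 in T or NK-like cells. All were over 0.1, the level taken for fitting the run block. Only the homeostasis runs entered this check, and the opposite pairing of so few runs gives the same r with a negative sign. The check therefore cannot settle whether the numbers pair the libraries, and it does not cover the pancreatitis run.

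The fits were tested on simulated data with 200 changed genes. Counts were drawn around shared proportions, without differences between runs or clusters. Shares recovered are of the changed genes that passed the low-count filter in the simulated data, so those it removed are not counted as missed. For EYFP in acinar-like cells (728 genes) 2.5%, 29.5% and 77.6% of such genes changed 2-fold, 4-fold and 8-fold were recovered (1 of 40, 13 of 44 and 38 of 49). There was 1 false call among 341 tested unchanged genes. For pancreatitis in EYFP negative acinar-like cells (2419 genes) 0% of genes changed 8-fold were recovered. For EYFP in ductal-like cells (6808 genes) 28.8%, 98.5% and 100% were recovered, in endothelial-like cells (7118 genes) 40.9%, 97.0% and 100%, and for pancreatitis in ductal-like cells (6302 genes) 6.15%, 28.4% and 65.0%. These fits gave 5, 5 and 4 false calls among 6245, 6663 and 5541 tested unchanged genes. Pericyte or smooth muscle, neutrophil, endocrine and erythroid-like cells were not tested for expression, since too few cells were kept in at least 1 library.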

Results

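Single pancreatic cells of R26[CA]30EYFP mice on the C57Bl/6J background were profiled by droplet-based single-cell RNA sequencing. EYFP, a yellow fluorescent protein, marked labelled cells, and each run gave 1 library of EYFP positive and 1 library of EYFP negative cells. Runs 1 and 2 came from homeostasis and run 3 from mice 9 days after cerulein, a secretagogue that causes acute pancreatitis when given in excess (50 ug/kg, 7 injections a day on 2 days). The 6 libraries therefore formed 4 groups, with 2 libraries per EYFP group in homeostasis and 1 per EYFP group in pancreatitis. Run 3 and pancreatitis cannot be told apart. Nothing in the labels says whether libraries came from separate animals, so p-values measure the spread between these libraries.

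Together the libraries held 8582 barcodes and 44833541 UMIs. EYFP negative runs 1, 2 and 3 held 3234578, 8008285 and 23658431 UMIs over 810, 2490 and 3593 barcodes. EYFP positive runs 1, 2 and 3 held 5855869, 1044718 and 3031660 UMIs over 1002, 220 and 467 barcodes. After filters on genes and mitochondrial UMIs and removal of called doublets, 436, 1759 and 1440 EYFP negative cells and 832, 187 and 234 EYFP positive cells were kept. Their median depth was 4711, 2560 and 5582 UMIs per cell in EYFP negative runs 1 to 3, against 5528, 3761 and 7386 in EYFP positive runs 1 to 3. Haemoglobin transcripts, the products of red blood cells, made up 62.7% of all UMIs of the EYFP negative pancreatitis library and 20.2% of those of the EYFP positive one, against 0.213% to 7.24% in homeostasis. Xist, the non-coding RNA of the inactive X chromosome, was seen without Y-linked transcripts in 351 EYFP negative and 671 EYFP positive cells of run 1, which had 0 cells with Y-linked transcripts alone. In run 2, 819 EYFP negative cells held Xist alone and 272 held Y-linked transcripts alone, with 57 and 48 in the EYFP positive library. In run 3, 5 and 0 cells held Xist alone, against 643 and 86 with Y-linked transcripts alone. The sex mix of the cells thus differed between runs and, with it, between conditions.

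The 21 clusters were named by fixed marker genes, and every class below is a marker-based likeness. Acinar-like cells, the enzyme-secreting cells of the exocrine pancreas, formed 2 clusters. Cluster 16 (525 cells) was led by Ctrb1, Reg1, Rnase1, Try4 and Zg16. Digestive enzymes supplied a median of 79.6% of its UMIs. Cluster 20 (41 cells) was led by Nupr1, Ctrc, Rbpjl and Mt1. It held a median of 11.1% enzyme UMIs and had 141900 CPM (counts scaled to the library sum) of the nuclear RNA Malat1, against 110 CPM in cluster 16. Ductal-like cells (cluster 13, 346 cells) were led by Spp1, Clu, Tm4sf4, Krt18 and Krt8. Endothelial-like (Plvap, Kdr, Flt1), B or plasma-like (Cd79a, Ms4a1, Igkc), T or NK-like (Trbc2, Cd3g, Nkg7), macrophage or monocyte-like (Lyz2, C1qa) and fibroblast-like cells (Dcn, Col3a1) made up most of the rest. Erythroid, pericyte or smooth muscle, endocrine and neutrophil-like clusters were smaller.

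The opening comparison asked which cell types carried the label. Acinar-like cells made up 20.9% ± 17.2 (SD, n = 3) of EYFP positive and 9.61% ± 13.9 (SD, n = 3) of EYFP negative cells, and ductal-like cells 11.6% ± 4.48 against 5.16% ± 3.92. Both classes had the higher share in the EYFP positive library of 3 of 3 runs. Fibroblast-like cells made up 1.99% ± 1.10 against 4.61% ± 1.85. They were lower in 3 of 3 runs, but by -0.005 percentage points in run 3, where the difference turned to 0.632 points with doublets kept and 1.03 points with all barcodes. Endothelial-like cells made up 33.6% ± 30.5 of EYFP positive and 31.4% ± 18.9 of EYFP negative cells. B or plasma-like cells made up 14.99% ± 10.04 against 25.2% ± 4.22, T or NK-like cells 10.8% ± 4.99 against 15.9% ± 6.18, and macrophage or monocyte-like cells 3.68% ± 2.62 against 4.53% ± 2.87. A two-sided exact permutation test cannot give a p under 0.1 with 3 against 3 libraries, so no class could pass 0.05. That smallest p of 0.1 was reached by the pericyte or smooth muscle-like share (0.258% against 0.930%, 34 cells) and the neutrophil-like share (0.0401% against 0.199%, 8 cells), both lower in 3 of 3 EYFP positive libraries. The p was 0.5 for acinar-like, 0.3 for ductal-like, 0.2 for fibroblast-like, 0.9 for endothelial-like, 0.2 for B or plasma-like and 0.4 for T or NK-like cells. Benjamini-Hochberg adjusted values over 11 classes were 0.611, 0.611, 0.55, 0.9, 0.55 and 0.611. Paired by run, the acinar-like difference was 2.73, 17.9 and 13.2 points and the ductal-like one 7.998, 5.60 and 5.65 points, and both had a sign-flip p of 0.25, the smallest that 3 pairs allow. With all deposited barcodes the acinar-like share was 29.0% against 6.76% (22.3 points, p = 0.1, two-sided exact permutation test). The acinar-like share was 1.83% (8 of 436 cells) and 1.31% (23 of 1759 cells) in EYFP negative runs 1 and 2, and 25.7% in EYFP negative run 3 (370 of 1440 cells, 95% exact binomial interval 23.4% to 28.0%). In the EYFP positive libraries it was 4.57% (38 of 832), 19.3% (36 of 187) and 38.9% (91 of 234, interval 32.6% to 45.5%). The sort for EYFP and the yield of each cell type on dissociation can both set these shares. The acinar-like difference of 11.3 percentage points ranged from 2.30 without EYFP positive run 3 to 19.5 without EYFP positive run 1, and the ductal-like one from 4.22 without EYFP negative run 3 to 9.00 without EYFP positive run 3. The sign of the endothelial-like difference turned without EYFP positive run 1 (-15.4 percentage points) or without EYFP negative run 3 (-8.14 points). So did that of macrophage or monocyte-like cells without EYFP negative run 1 (0.550 points) or without EYFP positive run 1 (0.385 points). The B or plasma-like difference was -20.4, 3.45 and -13.8 points in runs 1 to 3 and the T or NK-like one -10.4, 2.88 and -7.76 points, so run 2 went the other way in both. With libraries left out the first ranged from -15.1 to -5.04 points, the latter without EYFP positive run 1. The second ranged from -8.10 to -1.93 points, the latter without EYFP negative run 3.

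**Figure D1:**
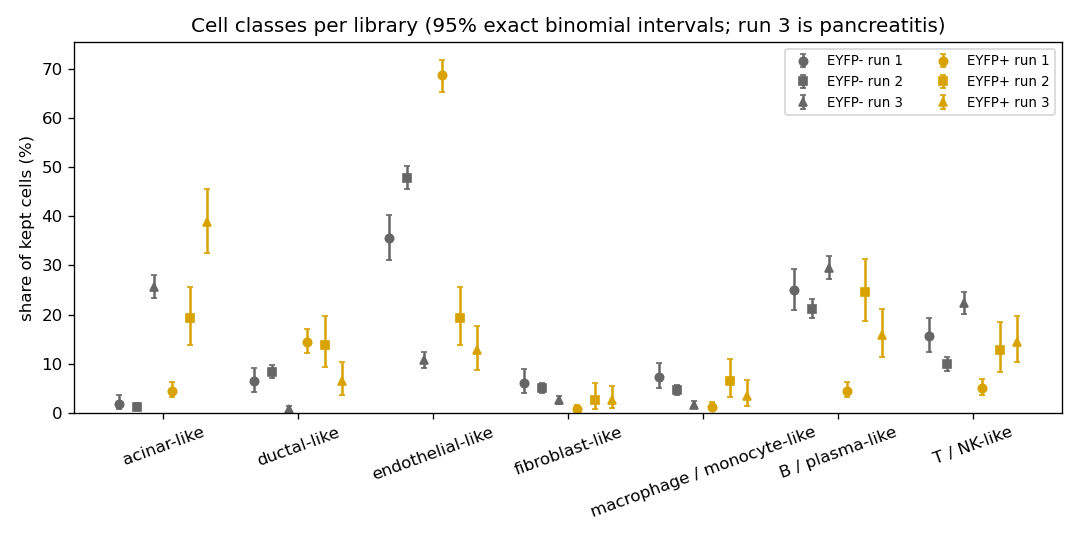
Share of kept cells in each of 7 marker-based classes (vertical axis, %), with 1 point per library and 95% exact binomial intervals; grey is EYFP negative, yellow EYFP positive, and triangles are the pancreatitis run. Acinar-like cells made up 25.7% and 38.9% of the 2 pancreatitis libraries and 1.31% to 19.3% of the 4 homeostasis libraries.

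The next comparison asked whether EYFP positive and EYFP negative acinar-like cells differed in expression across the 3 runs. The digestive enzyme gene Cpa1 (ENSMUSG00000054446, carboxypeptidase A1) differed by -0.17 ± 1.02 in log2 (± is the standard error of the fit throughout). Ptf1a (ENSMUSG00000026735), a transcription factor of acinar identity, differed by 0.79 ± 0.78. Igkc (ENSMUSG00000076609, the immunoglobulin kappa constant gene of B and plasma cells) had a value of -2.20 ± 0.83 and was lower in the EYFP positive library of 3 of 3 runs. The haemoglobin genes Hbb-bt (-3.86 ± 1.12), Hba-a2 (-3.83 ± 1.40), Hbb-bs (-3.10 ± 1.45) and Hba-a1 (-3.07 ± 1.52), whose near-identical copies make the split between genes uncertain, had the other lowest p-values in the negative direction. Of these, Hbb-bs was lower in 3 of 3 runs. In the other direction stood the immediate-early genes Fos (ENSMUSG00000021250, 2.21 ± 1.09) and Egr1 (ENSMUSG00000038418, 2.59 ± 1.35), the splicing factor gene Snrnp70 (2.53 ± 1.14), Rap1gap (1.86 ± 0.81) and Fam46c (1.23 ± 0.64). Each was higher in 3 of 3 runs.

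Of 728 genes tested, 0 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment; every gene named above had an adjusted p of 0.999). Under an unadjusted p of 0.05 stood 4 genes, and DESeq2 called 0. With run number as a block, 1 gene passed, Hbb-bt, at -3.99 and an adjusted p of 0.025. In cluster 16 alone, an alternative chosen after the data were seen, 5 genes passed, all lower in EYFP positive cells: Hbb-bs (-5.25), Hbb-bt (-4.48), Hba-a2 (-5.37), Hba-a1 (-4.86) and Igkc (-3.59). Acinar-like sums held 49994 to 3039175 UMIs per library. On simulated data of this comparison 77.6% of genes changed 8-fold and 29.5% of genes changed 4-fold were recovered among those that passed the low-count filter (38 of 49 and 13 of 44). Changed genes under the filter were not recovered. The simulation changed 200 of the 728 genes and held no differences between runs or clusters. With few changed genes the adjustment is stricter, so recovery can be lower than these shares.

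Across the fixed gene lists in acinar-like cells, 0 genes rose or fell in any list, both over all genes tested and when adjusted over the list alone. The 12 measured immediate-early and dissociation genes were all higher in EYFP positive cells (median 1.46), including Jund (1.64 ± 1.12) and Ier2 (1.47 ± 1.05), and 11 of 12 with library sizes computed without the enzyme genes. The list passed limma camera with its preset correlation (adjusted p = 0.00011), but not otherwise (adjusted p = 0.855 with an estimated correlation). EYFP positive run 2 held 271 of the 302 Fos UMIs and 146 of the 159 Egr1 UMIs of EYFP positive acinar-like cells. Cluster 20 supplied 31 of the 36 acinar-like cells of that library and 7 of the 23 of EYFP negative run 2. In cluster 16 alone the list had too few measured genes for a test. Of 47 cytosolic ribosomal protein genes, 35 were lower (median -0.20, Rpsa -0.76 ± 0.72, camera adjusted p = 0.00011; adjusted p = 0.855 with an estimated correlation), while cluster 16 alone gave 22 higher and 25 lower.

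The other lists did not pass camera for this comparison. Of 34 digestive enzyme genes, 14 were higher and 20 lower (median -0.08, adjusted p = 0.115), turning to 19 higher and 15 lower in cluster 16 alone. With the run block 7 were higher and 27 lower (adjusted p = 0.0366; adjusted p = 0.844 with an estimated correlation). The acinar transcription factors Rbpjl, Ptf1a and Xbp1 had values of 1.49 ± 1.22, 0.79 ± 0.78 and 0.18 ± 0.59 (adjusted p = 0.421). Of 22 secretory pathway and unfolded protein response genes, 15 were higher (median 0.34, adjusted p = 0.447). Of 6 genes of duct cells and acinar-to-ductal metaplasia, 4 were higher (median 0.20, adjusted p = 0.657), but 4 of 5 were lower in cluster 16 alone. Of 5 Reg family and acute-phase genes, which acinar cells raise on injury, 2 were higher (median -0.08, adjusted p = 0.76), turning to 3 higher with DESeq2's size factors. Of 45 nuclear oxidative phosphorylation genes 18 were higher (median -0.11, adjusted p = 0.421), and of 12 mitochondrially encoded genes 3 (median -0.23, adjusted p = 0.597). Higher were also 3 of 5 oxidative stress genes (median 0.14, adjusted p = 0.76, even in cluster 16 alone) and 5 of 7 interferon and antigen presentation genes (median 0.28, adjusted p = 0.657, with a negative sign in camera and 0 of 5 higher in cluster 16 alone).

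In homeostasis alone, with 2 libraries per EYFP group, 0 of 2419 genes passed (edgeR, 34 under an unadjusted p of 0.05, 0 by DESeq2). Igkc again had a low value (-3.36 ± 1.58, adjusted p = 1, lower in both runs), and Cpa1 stood at -0.13 ± 2.86. The ratios of summed CPM, with counting intervals, were 15.7 (4.19 to 132) for C2cd4b, which rested on 2 UMIs in EYFP negative cells, and 19.3 (3.28 to 780) for the stress-induced transcription factor gene Atf3, which rested on 1 UMI. Spp1 (osteopontin, a duct cell product) had a ratio of 7.78 (3.46 to 21.7). The ribosomal protein gene Rps3 stood at 0.67 ± 1.73. A single library decided these counts. Without EYFP positive run 1, which leaves EYFP positive run 2 and its cluster 20 cells as the only labelled homeostasis library, 175 genes passed and Rps3 turned to -2.01. Without EYFP positive run 2, 2 genes passed. Cluster 16 alone gave 1 gene, Igkc (-4.73, adjusted p = 0.0047).

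Markers proposed for pancreatic progenitor cells and markers of division were sparse in acinar-like cells of both EYFP groups. Tert and Dclk1 had 0 UMIs in all 6 libraries. Mki67 had 1 UMI, in EYFP negative run 3, and Bmi1 had 7 UMIs in EYFP negative and 0 in EYFP positive cells. Stmn1, a microtubule regulator proposed as a progenitor marker, had 53 UMIs in EYFP negative cells, 50 of them in run 3, and 8 in EYFP positive cells, all in run 3. The 3 measured genes of the progenitor list were lower in EYFP positive cells (Ly6e -0.54 ± 0.61, Tff2 -0.43 ± 0.91, Spink1 -0.34 ± 0.94; camera adjusted p = 0.115; adjusted p = 0.855 with an estimated correlation). The duct genes Krt19 and Sox9 had 42 and 12 UMIs in EYFP negative and 11 and 11 UMIs in EYFP positive cells. Acinar-like cells held 49994, 108830 and 3039175 UMIs in EYFP negative runs 1 to 3, against 278321, 75575 and 807462 in the EYFP positive runs. Counts of single genes here therefore do not compare levels between groups or runs.

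The share of acinar-like cells with UMIs of at least 2 of 20 mitotic genes, after thinning every cell to 1000 UMIs, asked whether labelled acinar cells divided more. It was 0 of 8, 1 of 19 and 2 of 363 cells in EYFP negative runs 1 to 3, or 1.94% ± 2.89 (SD, n = 3). It was 0 of 38, 0 of 26 and 0 of 85 cells in the EYFP positive runs, which allow shares of up to 7.89%, 11.5% and 3.53% (p = 0.4, two-sided exact permutation test). Thinning left out 0, 4 and 7 EYFP negative and 0, 10 and 6 EYFP positive cells with fewer UMIs. Without thinning the shares were 2.35% ± 2.20 and 1.10% ± 1.90 (p = 0.7, two-sided exact permutation test). A difference in dividing acinar-like cells was not detectable at this depth. Free RNA adds UMIs to cells that do not make them, and its part in these shares was not measured. Thinned T or NK-like cells gave 0% in all EYFP negative and 2.85% ± 3.05 in EYFP positive libraries. That difference had a p of 0.4 (two-sided exact permutation test). Their own cell cycle list was higher with the label by camera with its preset correlation only, and not without cluster 19. A difference in their own division was thus not settled, so T or NK-like cells were not taken as a background level for free RNA.

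Pancreatitis was compared with homeostasis in EYFP negative acinar-like cells, 1 library (370 cells, all of cluster 16) against 2 (8 cells of cluster 16, and 23 cells, 7 of them of cluster 20). Genes of the Reg family, secreted lectins that acinar cells make after injury, were higher: Reg2 (ENSMUSG00000023140) held 4388 UMIs in the pancreatitis library and 1 in homeostasis, a ratio of summed CPM of 229 (counting interval 41.1 to 9059). Reg3b (ENSMUSG00000071356) held 642 against 1, a ratio of 33.6 (6.00 to 1327), and Reg3g (ENSMUSG00000030017) held 224 against 0, at least 3.90-fold higher. Bounds of this kind set the group at 0 to a floor of 3 counts over the group. Trypsin-like transcripts of near-identical copies, whose reads cannot be split with certainty, stood alike. Gm2663 was at least 22.0-fold higher (1264 UMIs against 0), 1810009J06Rik at least 17.9-fold higher (1028 against 0), and Prss1 had a ratio of 22.0 (3.93 to 871). Cpa1 stood at -0.01 ± 3.50. Immediate-early genes, which stress and tissue dissociation switch on, were low, with Egr1 at least 140-fold lower (0 UMIs against 22), Fosb at a ratio of 0.00169 (4.14e-05 to 0.0101) and Fos at 0.00341 (0.000678 to 0.0106). Tnrc6a (0.0121) and the endothelial phosphatase gene Ptprb (0.00871) were low too. Xist was at least 383-fold lower (0 UMIs against 60), with the sex mix of the libraries.

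None of these genes passed over all genes. edgeR called 0 of 2419 genes (141 under an unadjusted p of 0.05; adjusted p was 0.329 for Gm2663, 0.357 for 1810009J06Rik, 0.392 for Tnrc6a and 0.469 for Ptprb). DESeq2 called 20, 8 higher and 12 lower, among them Reg2 (8.08), Jun (-5.60) and Malat1 (-6.59). In cluster 16 alone 16 genes passed, 10 higher and 6 lower, with Reg2 at 7.52 (adjusted p = 0.0001), Reg3b at 4.73 (adjusted p = 0.018), Gm5771 at 4.96 and Gm10334 at 4.11 of the trypsin-like copies, and Hba-a1 at 6.23. Lower were Igkc at -5.70, Ighm at -5.10 and mt-Nd3 at -3.54. Leaving out libraries moved the count to 55 without EYFP positive run 1, 52 without EYFP positive run 2 and 7 without EYFP negative run 1. The lone pancreatitis library was assumed to vary like the others. In simulated data of this comparison 0% of genes changed 8-fold were recovered, so a count of 0 says little here.

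As groups, the 5 measured Reg genes were all higher in EYFP negative pancreatitis cells (median 6.05, or 2.20 with the gene at 0 in homeostasis set to its bound), also under every other scaling. Of them 3 rose when adjusted over the list alone against 0 over all genes (camera adjusted p = 2.65e-05; adjusted p = 0.616 with an estimated correlation). All 47 cytosolic ribosomal protein genes (median 1.41, camera adjusted p = 0.000171; adjusted p = 0.788 with an estimated correlation) and all 47 nuclear oxidative phosphorylation genes, which code for respiratory chain subunits (median 1.93, camera adjusted p = 2.5e-11; adjusted p = 0.616 with an estimated correlation), were higher, and 34 and 41 of them in cluster 16 alone. The median of all genes was 0.35 with TMM scaling and -0.29 with DESeq2's size factors, under which the medians of these lists were 0.73 and 1.24. All 12 mitochondrially encoded genes were lower under each scaling (median -2.12, camera adjusted p = 6.48e-05; adjusted p = 0.616 with an estimated correlation), and in cluster 16 alone 3 of them fell. Of 26 immediate-early genes 20 were lower (median -1.79, unchanged with genes at 0 set to their bound; camera adjusted p = 1.26e-06; adjusted p = 0.616 with an estimated correlation), and 2 fell when adjusted over the list alone, while 4 of the 6 measured in cluster 16 alone were lower. Of 9 interferon and antigen presentation genes 7 were lower (median -1.48, camera adjusted p = 0.0227; adjusted p = 0.616 with an estimated correlation), and H2-Eb1 fell when adjusted over the list alone.

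The remaining lists did not pass camera in EYFP negative cells. Of 35 digestive enzyme genes 28 were higher (median 0.69, adjusted p = 0.185), a direction that turned in cluster 16 alone (9 higher, 25 lower) and was even with DESeq2's size factors (18 higher, 17 lower). Of 26 secretory pathway genes 18 were higher (median 0.50, adjusted p = 0.539), turning to 9 with DESeq2's size factors. Of 12 duct and metaplasia genes 10 were higher (median 1.22, or 0.76 with Krt19 at its bound; adjusted p = 0.185), with Spp1 at 1.14 ± 1.62, Sox9 at 0.23 ± 2.45 and Krt19 at 42 UMIs against 0. Of 8 acinar transcription factor genes 7 were lower (median -0.50, adjusted p = 0.39; Ptf1a -0.55 ± 1.44). Of 9 oxidative stress genes 7 were higher (median 0.92, or 0.55 with bounds, adjusted p = 0.113, but 3 of 7 in cluster 16 alone). Of 8 progenitor markers 5 were higher (median 0.13, adjusted p = 0.549), turning to 3 with DESeq2's size factors. The 3 cell cycle genes were higher (median 1.24, adjusted p = 0.261; 2 with DESeq2's size factors), the 3 inflammatory genes lower (median -2.75, adjusted p = 0.162), and the 4 p53 target genes even (median -0.20, adjusted p = 0.757). Of the sex-linked genes 2 were higher and Xist lower (camera adjusted p = 0.39).

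In EYFP positive acinar-like cells the same contrast, 1 pancreatitis library of 91 cells against homeostasis libraries of 38 and 36 cells, gave high Reg and trypsin-like values too. Reg3b held 140 UMIs against 1, a ratio of 61.4 (10.8 to 2441). Reg3g held 54 against 0, at least 7.89-fold higher, and Reg2 stood at 6.24 ± 2.40. The trypsin-like pair 1810009J06Rik and Gm2663 was at least 69.0-fold and 67.6-fold higher (ENSMUSG00000094808 and ENSMUSG00000096525), and Prss1 had a ratio of 86.8 (15.4 to 3445). At 0 UMIs in the pancreatitis library stood C2cd4b (at least 53.2-fold lower), the heat shock gene Hspa1a (at least 47.9-fold), Atf3 (at least 32.7-fold), Fosb (at least 89.0-fold), Slc6a9 (at least 38.8-fold), AC149090.1 (at least 41.1-fold), Klf4 (at least 16.0-fold), Socs3 (at least 20.5-fold) and Xist (at least 101-fold). Of the homeostasis cells, 31 of 36 in run 2 were of the Malat1-rich cluster 20. Cpa1 stood at 0.34 ± 3.45, Krt19 at -0.66 ± 1.68, Sox9 at -1.80 ± 2.09 and Spp1 at -3.15 ± 1.81.

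edgeR called 0 of 2419 genes in this contrast (243 under an unadjusted p of 0.05; lowest adjusted p 0.0799, for 1810009J06Rik, Reg3g and Gm2663, and 0.176 for Reg3b, C2cd4b, Slc6a9 and AC149090.1), and DESeq2 called 32, 6 higher and 26 lower. In cluster 16 alone 10 genes passed: 1810009J06Rik, Gm2663, Gm10334 (5.21), Prss1 (5.84), Gm5771 (4.72), Reg2 (5.01, adjusted p = 0.0023), Reg3b (5.34, adjusted p = 0.0064) and Reg3g were higher, and Ptprb (-5.97) and Spp1 (-3.53, adjusted p = 0.031) lower. Without EYFP positive run 1, 389 genes passed, and without EYFP positive run 2, 19.

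By list, the 5 Reg genes were higher in EYFP positive pancreatitis cells under every scaling (median 6.24, or 2.98 with bounds; camera adjusted p = 1.03e-06), 3 of them rising when adjusted over the list alone. All 26 immediate-early genes were lower (median -5.98, or -4.26 with the 12 genes at 0 in one group set to their bound; camera adjusted p = 7.44e-12), and 14 fell when adjusted over the list alone, while all 6 measured in cluster 16 alone were lower (median -0.98). All 47 nuclear oxidative phosphorylation genes (median 1.97, camera adjusted p = 7.2e-16) and all 47 ribosomal protein genes (median 1.17, camera adjusted p = 5.71e-09) were higher, as were 43 and 33 of them in cluster 16 alone. The median of all genes was -0.48 with TMM scaling and -1.50 with DESeq2's size factors. Of 35 digestive enzyme genes 32 were higher (median 0.82, camera adjusted p = 9.23e-07), with 19 of 34 in cluster 16 alone, and 20 of 26 secretory pathway genes (median 0.53, camera adjusted p = 0.0491), turning to 9 with DESeq2's size factors. For each list that passed camera here, the sex-linked genes included (0 of 3 higher, adjusted p = 0.0474), the adjusted p was 0.687 with an estimated correlation, and over all genes 0 members rose or fell. Of 12 duct and metaplasia genes 5 were higher (median -0.39, adjusted p = 0.889; 4 of 7 in cluster 16 alone), and Klf4 fell when adjusted over the list alone. Of 12 mitochondrially encoded genes 11 were lower (median -0.41, adjusted p = 0.892), and of 8 acinar transcription factor genes 6 (median -0.63, adjusted p = 0.889).

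**Figure D2:**
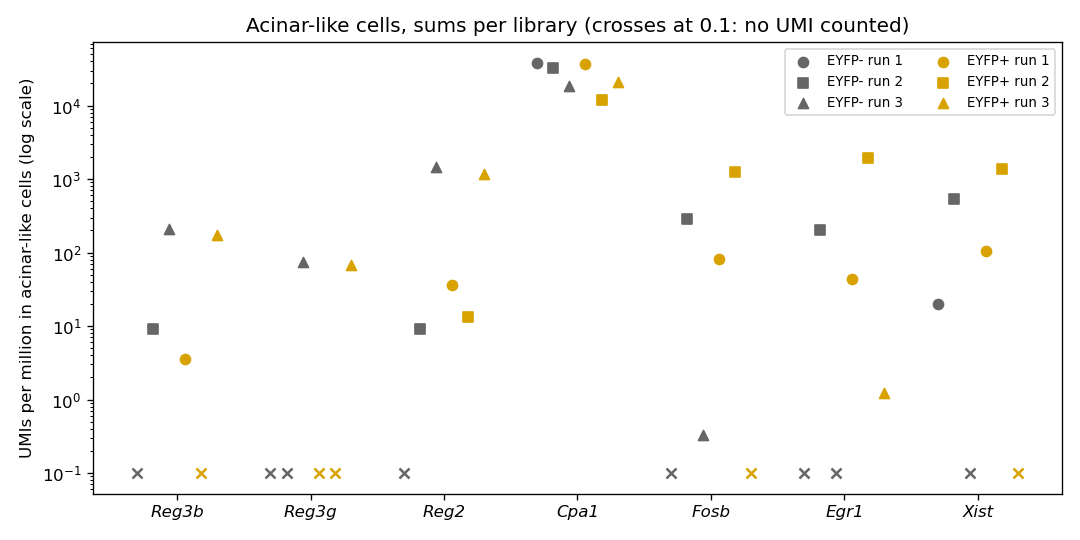
CPM in acinar-like cells (vertical axis, log scale) for Reg3b, Reg3g, Reg2, Cpa1, Fosb, Egr1 and Xist, with 1 point per library; grey is EYFP negative, yellow EYFP positive, triangles are the pancreatitis run, and crosses at the foot mark 0 UMIs. Reg3g had 0 UMIs in the 4 homeostasis libraries, against 224 and 54 UMIs in the pancreatitis libraries.

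Whether labelled and unlabelled acinar-like cells responded differently was tested as an interaction. edgeR called 0 of 2419 genes (25 under an unadjusted p of 0.05, 0 by DESeq2), so the different counts of list members in the EYFP groups are not shown to differ. Without EYFP positive run 1, 82 genes passed, and with doublets kept 1 gene.

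In ductal-like, endothelial-like and T or NK-like cells, classes that do not make immunoglobulin, EYFP positive libraries held less Igkc RNA. In ductal-like cells Igkc fell by 3.998 on the log2 scale (SE 0.32, adjusted p = 3.75e-07). It went from 480, 345 and 70.7 CPM in EYFP negative runs 1 to 3 to 28.9, 13.3 and 8.05 CPM in the EYFP positive runs. Ighm, the heavy chain of immunoglobulin M, fell by 4.02 (SE 0.54, adjusted p = 0.00041). Hba-a2 (-4.85 ± 0.59, adjusted p = 0.000144), Hba-a1 (-4.78 ± 0.62), Hbb-bt (-4.04 ± 0.48) and Hbb-bs fell with them, each named gene in 3 of 3 runs. In endothelial-like cells Igkc (-4.18 ± 0.32, adjusted p = 8.36e-07), Ighm (-3.65 ± 0.37, adjusted p = 5.04e-05), the cytochrome c oxidase gene mt-Co3 (-1.40 ± 0.25, adjusted p = 0.0335), the joining chain gene Jchain and the fibroblast proteoglycan gene Dcn (-5.82) fell. In T or NK-like cells Igkc fell (-4.52 ± 0.44, adjusted p = 0.000216) and Stfa3, a stefin gene, rose. Stfa3, Hbb-bs, Jchain and Dcn were named after their values were seen, to complete these short lists.

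These were all the calls of edgeR: 6 of 6808 genes in ductal-like, 5 of 7118 in endothelial-like and 2 of 5233 in T or NK-like cells. There were 0 of 6670 in B or plasma-like cells (241 under an unadjusted p of 0.05, 3 by DESeq2) and 0 of 2576 in macrophage or monocyte-like cells of homeostasis (163 under an unadjusted p of 0.05, 6 by DESeq2). The run block gave 9 genes in endothelial-like cells, where Dcn was lost (adjusted p = 0.176), 15 in T or NK-like and 13 in B or plasma-like cells. By DESeq2 Igkc and Ighm passed in ductal-like cells, but the 4 haemoglobin genes did not (adjusted p from 0.175). With stricter cells Dcn (adjusted p = 0.0521) and mt-Co3 (adjusted p = 0.0589) did not pass in endothelial-like cells. Leaving out libraries gave 18 genes in ductal-like cells without EYFP negative run 3 and 20 without EYFP positive run 3. Hbb-bs was lost without EYFP negative run 2 (adjusted p = 0.0806), and Ighm fell under the low-count filter without EYFP negative run 1 or run 2. In endothelial-like cells it gave 7 genes without EYFP negative run 1, of which Igkc and Dcn were shared with the full fit. It gave 1 gene without EYFP negative run 2, 11 without EYFP negative run 3 and 1 without EYFP positive run 1. Igkc passed in each of these fits, while mt-Co3 was lost whichever of the 6 libraries was left out (adjusted p from 0.0510). With clusters left out in turn Igkc, Ighm and mt-Co3 passed each time, Jchain was lost without cluster 6 (adjusted p = 0.126), and Dcn without cluster 4 (adjusted p = 0.0559) and, under the low-count filter, without cluster 0 or 6. T or NK-like cells gave 5 genes without EYFP negative run 1, where Igkc fell under the low-count filter. Without EYFP negative run 2 they gave 2 genes, Hbb-bt and Hba-a2, with neither Igkc, under the filter again, nor Stfa3 (adjusted p = 0.0921). They gave 15 without EYFP negative run 3, 1 without EYFP positive run 1, 6 without EYFP positive run 2 and 18 without EYFP positive run 3, and Stfa3 was under the filter without EYFP positive run 1 or run 2. With clusters left out in turn Igkc passed each time, and Stfa3 was lost without cluster 11 (adjusted p = 0.196) and was under the filter without cluster 19. B or plasma-like cells gave 4 genes without EYFP negative run 1 and 3 without EYFP positive run 2, and macrophage or monocyte-like cells 12 without EYFP negative run 1, 49 without EYFP negative run 2 and 8 without EYFP positive run 2.

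Stress, cell cycle, mitochondrial and enzyme gene lists differed with the label in some classes by camera with its preset correlation, and none of these calls held with an estimated one. In T or NK-like cells 23 of 24 immediate-early genes were higher in EYFP positive libraries (Dusp1 1.49 ± 0.32; camera adjusted p = 2.59e-11, 4 rose when adjusted over the list alone; adjusted p = 0.535 with an estimated correlation). Higher too were 14 of 15 cell cycle genes (Top2a, a mitotic topoisomerase gene, 3.07 ± 0.62; camera adjusted p = 6.95e-06, 4 rose when adjusted over the list alone; adjusted p = 0.535 with an estimated correlation). Cluster 19 held 46.5%, 8.33% and 29.4% of the T or NK-like cells of EYFP positive runs 1 to 3 and 19.1%, 12.0% and 28.3% of the EYFP negative ones. Without it 4 of 8 cell cycle genes were higher (camera adjusted p = 0.897), while the immediate-early list passed with each cluster left out (camera adjusted p up to 2.65e-07). The duct and the progenitor lists also passed camera with its preset correlation in T or NK-like cells, but not with the run block. In B or plasma-like cells 22 of 23 immediate-early genes were higher (camera adjusted p = 1.59e-08, 3 rose when adjusted over the list alone; adjusted p = 0.639 with an estimated correlation). Their make-up differed as well. The plasma-like cluster 1 held 26.3%, 21.7% and 2.70% of the cells in EYFP positive runs 1 to 3 against 11.01%, 8.60% and 0.235% in the EYFP negative runs. By UMIs it held 43.9%, 18.2% and 4.88% of the class against 36.5%, 37.5% and 0.0674%, so run 2 went the other way. Its cells had a median of 2600 and 903 UMIs in EYFP positive runs 1 and 2, against 23960 and 18540 in the EYFP negative ones. Cluster 3 held 39.5%, 28.3% and 16.2% of the cells against 35.8%, 65.1% and 21.4%. The list passed without cluster 1 (22 of 23 higher, camera adjusted p = 1.20e-10; adjusted p = 0.629 with an estimated correlation) and without cluster 3 (22 of 23, camera adjusted p = 2.90e-06; adjusted p = 0.485 with an estimated correlation). Of the 13 mitochondrially encoded genes 9 were lower in endothelial-like cells (camera adjusted p = 1.65e-06, 1 fell over all genes and 7 when adjusted over the list alone; adjusted p = 0.761 with an estimated correlation; camera adjusted p up to 3.10e-05 with clusters left out) and 9 in ductal-like cells (camera adjusted p = 8.08e-05, 0 fell over all genes and 8 when adjusted over the list alone; adjusted p = 0.984 with an estimated correlation). Barcodes with over 20% mitochondrial UMIs, a sign of damaged cells, also differed with the label. They were 365 of 810 and 570 of 2490 in EYFP negative runs 1 and 2, against 94 of 1002 and 18 of 220 in the EYFP positive ones. Run 3 went the other way (39 of 3593 against 103 of 467). All 21 digestive enzyme genes were lower in EYFP positive ductal-like cells (median -1.08, camera adjusted p = 2.47e-15, 0 fell over all genes or when adjusted over the list alone; adjusted p = 0.984 with an estimated correlation), where 1 cell of EYFP negative run 3 held 95.2% of the enzyme UMIs of that library's ductal-like cells. In B or plasma-like cells Egr1 (1.52 ± 0.34), Spp1 (2.69 ± 0.61), mt-Co3 (-1.23 ± 0.21), Ighg3 (-3.08 ± 0.54) and Igha (-6.60 ± 1.38) did not pass, at adjusted p from 0.372 to 0.72. In macrophage or monocyte-like cells of homeostasis Ccrl2 (2.06 ± 0.46), Jund (1.17 ± 0.30), Tmem123 (-3.00 ± 0.39), mt-Co3 (-1.95 ± 0.29) and the chemokine gene Cxcl9 (at least 8.08-fold lower, 0 UMIs against 105) did not pass, at adjusted p from 0.456 to 0.545.

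Pancreatitis was compared with homeostasis in the other cells of the EYFP negative libraries, 1 library against 2. In the 11 ductal-like cells of the pancreatitis library digestive enzyme genes were far higher. Gp2, a zymogen granule glycoprotein gene, rose at a ratio of summed CPM of 135 (42.4 to 691, 32 UMIs against 3, adjusted p = 2.96e-25), with Try5 (6.12 ± 0.51), Klk1 (5.70 ± 0.48), Ctrb1 (5.66 ± 0.58) and Reg1 (5.37 ± 0.44). Of 24 measured enzyme genes 23 rose over all genes and 24 when adjusted over the list alone (median 4.56, camera adjusted p = 1.89e-315; adjusted p = 0.279 with an estimated correlation). A single cell held 6692 UMIs, or 95.2%, of these cells' enzyme UMIs. Without it Ctrb1 (2.13, adjusted p = 0.00015), Reg1 (2.60, adjusted p = 0.00085), Try5 (1.99) and Cela1 (1.84) still rose, and the count dropped from 64 genes (48 higher, 16 lower, of 6302) to 18 (14 higher, 4 lower). Among genes that fell, the complement gene C3 was at least 2.68-fold lower, Igfbpl1 at least 3.55-fold, Ptprb at least 3.81-fold, the circadian repressor gene Nr1d1 at least 3.13-fold and Xist at least 27.6-fold. The p53 target list had 12 of 14 genes higher (2 rose over all genes, 5 when adjusted over the list alone; camera adjusted p = 4.26e-05; adjusted p = 0.751 with an estimated correlation). Most of these cells were shallow, with a median of 1330 UMIs, against 11710 and 5592 in homeostasis runs 1 and 2. The tested CPM are of sums, however, which held 98984 UMIs over the 11 cells. In homeostasis the sums held 279449 UMIs over 28 cells and 976864 over 146. The summed cells were thus not shallower on average than those of run 2, and a few deep cells weigh most. How depth bears on the rises left without the richest cell was not tested. The median of 39 enzyme UMIs per ductal-like cell was 2.79 times that of T or NK-like cells in the pancreatitis library. The rises left without the richest cell are therefore not shown to be a change within duct cells.

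In endothelial-like cells after pancreatitis the antigen presentation genes Cd74 (-4.03), H2-Ab1 (-4.11), H2-Eb1 (-3.66) and H2-Aa (-2.89) fell. Of 28 genes of the interferon list 4 fell over all genes and 5 when adjusted over the list alone (camera adjusted p = 2.97e-05; adjusted p = 0.895 with an estimated correlation). H2-Ab1 also fell in T or NK-like cells, where it was lost without their NK-like cluster. H2-Eb1 fell in EYFP negative acinar-like cells when adjusted over the list alone. Igkc, which endothelial-like and T or NK-like cells do not make, fell beside H2-Ab1 in both. Less RNA from other cells was therefore not told apart from a change within endothelial-like cells. Igkc fell by 4.72 (SE 0.66, adjusted p = 1.29e-09), Jchain was at least 5.45-fold lower, and Nr1d1 and Spp1 had ratios of 0.0174 (0.00044 to 0.0977) and 0.0435 (0.00109 to 0.246), with 1 UMI each in the pancreatitis library. Most homeostasis UMIs of both came from run 2. Nr1d1 stood at 32.1 CPM in run 1 and 165 CPM in run 2, where clock output genes were highest, against 2.41 CPM after pancreatitis, and Spp1 at 18.9 and 64.5 against 2.41 CPM. Neither passed in the fit of all 6 libraries (adjusted p = 0.758 for Nr1d1 and 0.636 for Spp1) or in that fit without EYFP negative run 2 (adjusted p = 0.665 and 0.998). Map1b, a microtubule-associated protein gene, rose (2.05 ± 0.44, adjusted p = 0.00119), as did Hba-a2 (4.11 ± 0.50), Hba-a1 (3.91 ± 0.51), Hbb-bs (3.84 ± 0.53) and the Y-linked Ddx3y (1.95 ± 0.38), while Xist was at least 65.5-fold lower. edgeR called 25 of 7800 genes, 9 higher and 16 lower, DESeq2 called 2, and a fit of all 6 libraries called 3. Leaving out libraries from that fit gave 23 genes without EYFP negative run 1, 21 without EYFP negative run 2, 25 without EYFP positive run 1 and 26 without EYFP positive run 2. The class pools 5 clusters of differing shares (cluster 0 held 23 of 155 and 298 of 842 cells in homeostasis runs 1 and 2 against 63 of 155), and leaving out each in turn gave 20 to 30 genes. Map1b (adjusted p = 0.125), Hba-a1 (adjusted p = 0.306) and Hbb-bs (adjusted p = 0.14) were lost without cluster 0, and Map1b (adjusted p = 0.376) and Jchain (adjusted p = 0.096) without cluster 6.

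The T or NK-like cells pool clusters 11, 14, 18 and 19, whose shares differed. The NK-like cluster 14 (Gzma, Tyrobp, Fcer1g) held 82 of 321 cells of the pancreatitis library against 9 of 68 and 12 of 175 in homeostasis runs 1 and 2, and cluster 18 held 67 against 17 and 79. Hspa1a rose by 3.14 ± 0.41 (adjusted p = 1.46e-11), and by 2.94 to 3.24 with each cluster left out in turn (adjusted p up to 0.00123). Phlda1 rose by 2.93 ± 0.41 (adjusted p = 1.12e-09), and by 2.45 to 3.52 with clusters left out. Of 25 immediate-early genes 8 rose over all genes and 12 when adjusted over the list alone (camera adjusted p = 5.75e-27; adjusted p = 0.744 with an estimated correlation). H2-Ab1 (-4.92 ± 0.57), Igkc (-5.07 ± 0.54) and Xist (-5.67 ± 0.67) fell. H2-Ab1 was lost without cluster 14 (-3.91, adjusted p = 0.197), and Alas2 was under the low-count filter without cluster 18. Spp1 and the endothelial and adipocyte fatty acid binding protein gene Fabp4 had ratios of 0.0164 (0.00194 to 0.0614) and 0.0182 (0.00216 to 0.0686). The Y-linked Ddx3y (4.48 ± 0.56) and Eif2s3y (3.95 ± 0.55) and the erythroid gene Alas2 (2.89 ± 0.51) rose. edgeR called 73 of 7410 genes, 42 higher and 31 lower, against 37 with DESeq2's size factors (18 higher, 19 lower), 8 by DESeq2 and 7 in a fit of all 6 libraries. Leaving out libraries from that fit gave 22 genes without EYFP negative run 1, 3 without EYFP negative run 2 and 38 without EYFP positive run 2.

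In fibroblast-like cells, the matrix-producing cells of the stroma, the monocyte-attracting chemokine gene Ccl7 rose (3.17 ± 0.55, adjusted p = 3.24e-06), beside Hba-a2 (6.15 ± 0.61), Hba-a1 (6.09 ± 0.62), Hbb-bs (5.50 ± 0.64) and Hbb-bt (4.06 ± 0.51). The chemokine-scavenging receptor gene Ackr3 was at least 17.4-fold lower, Sbsn at least 10.4-fold, Smpd3 at least 9.41-fold and Cadm3 at least 9.12-fold, and Xist at least 132-fold. Of 31 extracellular matrix genes 20 were higher and 11 lower (median 0.46, camera adjusted p = 0.551), 1 fell over all genes and 2 when adjusted over the list alone, Fn1 (-3.52) and Col14a1 (-1.85). All 47 ribosomal protein genes were lower (median -0.75, camera adjusted p = 2.17e-11, 0 fell; adjusted p = 0.931 with an estimated correlation). edgeR called 80 of 5271 genes, 17 higher and 63 lower, and DESeq2 called 12.

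In macrophage or monocyte-like cells the chemokine gene Ccl5 had a ratio of 0.00493 (0.000125 to 0.0275, adjusted p = 0.018). Gm42418, an rRNA-overlapping gene, fell by 2.92 (SE 0.27, adjusted p = 0.018), and Xist was at least 41.4-fold lower, which makes the 3 calls of edgeR among 4385 genes. The dendritic cell migration genes Fscn1 and Ccr7 were at least 25.2-fold and 14.97-fold lower (adjusted p = 0.0651 for both). With DESeq2's size factors 0 genes passed (376 under an unadjusted p of 0.05), and DESeq2 called 14. The B or plasma-like cells differed in make-up. The plasma-like cluster 1, led by Igkc and Jchain, held 12 of 109 and 32 of 372 of them in homeostasis runs 1 and 2 (36.5% and 37.5% of their UMIs), but 1 of 426 in the pancreatitis library (0.0674%). In the whole class edgeR called 0 of 9306 genes (550 under an unadjusted p of 0.05; adjusted p 0.758 for the genes named here) and DESeq2 called 101. Of 45 cell cycle genes 44 were lower (median -2.95, or -2.83 with bounds), with Cenpf at least 55.9-fold lower, and 11 fell when adjusted over the list alone (camera adjusted p = 2.39e-40; adjusted p = 0.777 with an estimated correlation). Of 27 secretory pathway genes 24 were lower (median -1.32, Edem1 -3.31 ± 0.26; camera adjusted p = 6.17e-20, 6 fell and 1 rose when adjusted over the list alone; adjusted p = 0.777 with an estimated correlation), beside Iglv1 (-5.15 ± 0.32), Xist (-5.72 ± 0.37) and Eaf2 (-4.23 ± 0.29). Without cluster 1 neither list differed. Of 17 cell cycle genes then measured 6 were lower (median 0.11, camera adjusted p = 0.494), and of 25 secretory pathway genes 13 (median -0.06, camera adjusted p = 0.266). Edem1 stood at -0.39 and Iglv1 at 0.23, Cenpf and Eaf2 were under the low-count filter, and Xist fell (-5.89). edgeR called 102 of 8283 genes there, 46 higher and 56 lower, 115 without cluster 2 and 0 without cluster 3. In the whole class Ppp1r15a, a stress-induced phosphatase subunit gene, stood at 2.58 ± 0.35 and Coq10b at 2.00 ± 0.22, and without cluster 1 they rose (2.18 and 1.83). A fit of all 6 libraries called 42 genes in B or plasma-like cells, and leaving out libraries from it gave 14 without EYFP negative run 1, 67 without EYFP negative run 2, 0 without EYFP positive run 1 and 0 without EYFP positive run 2.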

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

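No test here was planned before the values were seen. Barcodes most of whose UMIs came from haemoglobin genes, a signal in barcodes that the report's comparisons mostly leave out, made up 59.2% of the barcodes of EYFP negative run 3 (2127 of 3593) and 16.27% of those of EYFP positive run 3 (76 of 467). In homeostasis the shares were 0.741% and 4.30% in the EYFP negative and 0.399% and 3.18% in the EYFP positive libraries, which served as the comparison. Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, the haemoglobin genes of adult red blood cells, were also among the genes that rose in ductal-like, fibroblast-like and endothelial-like cells of EYFP negative run 3. The filter on genes removed 2104 barcodes of that library, and 82 erythroid-like cells of it were kept. Run 3 is the only pancreatitis run, so bleeding into the tissue, incomplete red cell removal and a difference between runs cannot be told apart, and no biological explanation was tested.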

How the results depend on the processing

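Cluster 16 alone, the clusters left out of other classes, the fit of all 6 libraries, the ductal-like cells without 1 cell, and in other classes DESeq2 and the cell filters, were chosen after the data were seen. Of 4720 values of named genes under alternatives, over 368 pairs of gene and comparison, 257 had another sign. Counted by calls, 294 values were called only under the alternative, 100 lost the main call and 1 called value reversed. Another 306, called in neither, moved by more than the main standard error, and 3995 stayed the same. Of the comparisons' own values 201 stayed near the main count of genes or lists or kept the sign of a difference in shares, 88 moved and 4 reversed. A count near the main one can hold other genes. The run block of shares and of cycling cells leaves the difference as it is and was counted as kept. The pancreatitis fits of other classes hold 3 libraries, and leaving 1 out leaves no residual degrees of freedom, so libraries were left out of the fit of all 6 only. No paired analysis was possible because pancreatitis was 1 run, which holds for the pancreatitis contrasts alone, since EYFP comparisons were also fitted with the run block and shares tested by sign-flip. Unless a sentence says otherwise, the cause was not tested.

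For EYFP in acinar-like cells over all runs the count of 0 genes moved to 5 in cluster 16 alone and to 1 with the run block. In homeostasis it moved to 1 in cluster 16 alone, stayed at 0 with the block (306 genes tested) and ranged from 0 to 175 when libraries were left out, 175 without EYFP positive run 1. Rps3 in homeostasis ranged from -2.01 (reversed, without EYFP positive run 1) to 1.22 against 0.67.

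For pancreatitis in EYFP negative acinar-like cells 0 genes became 20 with DESeq2, 1 with all barcodes, 4 in thinned sums, 16 in cluster 16 alone and 0 to 55 with libraries left out. In EYFP positive cells 0 became 2 with DESeq2's size factors, 32 with DESeq2, 12 in thinned sums, 10 in cluster 16 alone and 0 to 389 with libraries left out. The interaction count of 0 moved to 1 with doublets kept and ranged from 0 to 82. Of the gene lists camera called, with an estimated correlation 0 and with fry 0 were called for EYFP in acinar-like cells, and likewise 0 and 0 for pancreatitis in EYFP negative and 0 and 0 in EYFP positive cells. The block gave 3 lists for EYFP.

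For EYFP in other classes, ductal-like cells had 6 genes, 40 with no low-count filter, 3 with DESeq2 and 5 to 20 with libraries left out. Endothelial-like cells had 5 genes, 36 with no filter, 3 with stricter cells, 9 with the run block, 1 to 11 with libraries left out and 3 to 5 with clusters left out. B or plasma-like cells had 0 genes, 57 with no filter, 3 with DESeq2, 9 with all barcodes, 13 with the run block and 0 to 4 with libraries left out. T or NK-like cells had 2 genes, 77 with no filter, 10 with DESeq2, 8 with all barcodes, 15 with the run block, 1 to 18 with libraries left out and 1 to 6 with clusters left out. Macrophage or monocyte-like cells in homeostasis had 0 genes, 46 with no filter, 6 with DESeq2 and 0 to 49 with libraries left out. In ductal-like cells the run block gave 7 genes, adding Tm4sf1, and in endothelial-like cells it lost Dcn. By camera the block added the immediate-early list in ductal-like (adjusted p = 0.0136), the enzyme list in endothelial-like (adjusted p = 0.0346) and the ribosomal list in T or NK-like cells (adjusted p = 0.0242), where the duct and the progenitor lists were lost (adjusted p = 0.0509 for both). Other genes gained with the run block in endothelial-like, B or plasma-like and T or NK-like cells are in the counts above but are not named.

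For pancreatitis in other classes, ductal-like cells had 64 genes, 34 with DESeq2, 39 with all barcodes and 18 without the cell richest in enzymes. Endothelial-like cells had 25 genes, 2 with DESeq2, 41 with all barcodes, 3 in the fit of all 6 libraries, 21 to 26 with libraries left out of it and 20 to 30 with clusters left out. B or plasma-like cells had 0 genes, 101 with DESeq2, 267 with stricter cells, 302 with all barcodes, 42 in the fit of all 6 libraries and 0 to 67 with libraries left out of it. Leaving out clusters gave 102 without the plasma-like cluster 1, where the cell cycle (adjusted p = 0.494) and secretory lists (adjusted p = 0.266) were lost, 115 without cluster 2 and 0 without cluster 3. T or NK-like cells had 73 genes, 37 with DESeq2's size factors, 8 with DESeq2, 7 in the fit of all 6 libraries, 3 to 38 with libraries left out of it and 41 to 76 with clusters left out. Fibroblast-like cells had 80 genes and 12 with DESeq2. Macrophage or monocyte-like cells had 3 genes, 0 with DESeq2's size factors, 171 with no filter, 14 with DESeq2, 0 with stricter cells and 25 with all barcodes.

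The difference in the endothelial-like share ranged from -15.4 to 12.5 percentage points with libraries left out and that of the macrophage or monocyte-like share from -2.32 to 0.550, so neither has a settled sign. The acinar-like (2.30 to 19.5) and ductal-like (4.22 to 9.00) differences kept theirs. With all deposited barcodes the acinar-like difference was 22.3 points against 11.3 and the endothelial-like one 6.93 against 2.17. Depth also limits the acinar-like comparisons, since EYFP negative run 1 gave 8 cells and 49994 UMIs.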

Other observations

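The tests of split libraries, of the even spread of Igkc and of enzymes, of depth and of class composition were chosen only after the results were seen. Genes of the circadian clock differed between runs. The output genes Dbp, Nr1d1, Nr1d2 and Per3, which the clock drives, summed to 58.1, 268 and 20.1 CPM over all kept cells of EYFP negative runs 1, 2 and 3 and to 72.4, 341 and 31.6 CPM in the EYFP positive runs. Arntl and Npas2, which oscillate opposite to them, summed to 32.5, 15.03 and 11.2 CPM and to 51.8, 9.08 and 25.4 CPM. Run 2 thus had the highest sums of the output genes in both EYFP groups, and run 1 those of Arntl and Npas2. From run 1 to run 2 the output genes went from 58.5 to 519 CPM in EYFP negative and from 47.2 to 560 CPM in EYFP positive endothelial-like cells, and from 175 to 394 and from 125 to 571 CPM in ductal-like cells. B or plasma-like cells (28.5 to 26.6 CPM and 34.3 to 19.3 CPM) and T or NK-like cells (41.3 to 32.7 CPM and 88.5 to 38.7 CPM) showed no such rise.

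Mitochondrially encoded genes, which code for respiratory chain subunits, were lower after pancreatitis in 4 of 6 classes other than acinar-like cells in the EYFP negative libraries. Barcodes with over 20% mitochondrial UMIs, a sign of damaged cells, also differed: 365 of 810 and 570 of 2490 in homeostasis runs 1 and 2 against 39 of 3593 in the pancreatitis library. All 13 were lower in T or NK-like cells (median -0.83, camera adjusted p = 8.71e-08, 1 fell over all genes), in fibroblast-like cells (median -0.77, adjusted p = 0.000128, 1 fell) and in B or plasma-like cells (median -0.53, adjusted p = 0.0155, or 0.117 without cluster 3; 0 fell). In macrophage or monocyte-like cells all 12 measured were lower (median -1.09, adjusted p = 0.000129), and 8 fell when adjusted over the list alone. With an estimated correlation the adjusted p was 0.744, 0.931, 0.777 and 0.885. The list did not pass in ductal-like (median -0.27, adjusted p = 0.0582) or endothelial-like cells (7 of 13 lower, median -0.01, adjusted p = 0.628). Immediate-early genes were higher in B or plasma-like cells (24 of 28, median 0.81, adjusted p = 1.04e-08; adjusted p = 0.777 with an estimated correlation) and in macrophage or monocyte-like cells (21 of 26, median 0.93, adjusted p = 3.78e-06; adjusted p = 0.885 with an estimated correlation), beside T or NK-like (23 of 25, median 0.90) and ductal-like cells (20 of 26, median 0.34, adjusted p = 1.89e-06; adjusted p = 0.751 with an estimated correlation). In endothelial-like cells 17 of 27 were lower (median -0.28, adjusted p = 0.118), and fibroblast-like cells were near 0 (12 of 23 higher, median 0.12, adjusted p = 0.889).

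For this clock pattern, runs collected at different times of day predicted lower Arntl and Npas2 in run 2 than in run 1, and the ratio was 0.463 (95% counting interval 0.345 to 0.622) in EYFP negative and 0.175 (0.0794 to 0.338) in EYFP positive libraries, as predicted. Each ratio sets 1 library against 1, so the intervals do not cover the spread between libraries. In B or plasma-like cells Arntl went the other way in EYFP negative libraries (5.08 to 18.1 CPM). Depth predicted no more output UMIs per cell in the shallower library, run 2 in both EYFP groups, but they were 2.83 and 3.69 times those of run 1. At the same class composition the output genes were still 3.66 and 4.97 times higher in run 2, so a shift between classes is not the whole cause. Collection times are not given in the sources used here, the sex mix of the runs also differs and stays open, and no biological explanation was tested.

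Igkc and Ighm fell in EYFP positive ductal-like and endothelial-like cells, and haemoglobin genes in the ductal-like ones, classes that do not make them. RNA from other cells spread evenly over droplets was taken to predict Igkc CPM within 3-fold across classes of a library. The median ratio of the highest to the lowest class was 18.1 over all classes other than B or plasma-like cells with at least 10 cells. In ductal-like, endothelial-like and T or NK-like cells alone it was 1.42 (5 libraries), and both forms were run, so the answer depends on the classes taken. An even spread gives equal UMIs per droplet, whereas CPM also depend on the RNA content of a class. In EYFP positive run 2 the highest class, acinar-like, held 21 Igkc UMIs in 36 cells (278 CPM), and the lowest, ductal-like, 5 in 26 cells (13.3 CPM). The ratios of CPM therefore cannot decide on an even spread. Doublets with plasma cells remain open, since the top 5% of EYFP negative endothelial-like cells held 27.3% of their Igkc UMIs, where doublets predicted over 50% and their absence under 25%. Depth, which dilutes free RNA but does not lower its UMIs per cell, predicted equal UMIs per cell, but these were 8.46 times higher in EYFP negative libraries (median over the genes and classes, 4.59 to 16.5).

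Digestive enzyme UMIs in the 11 ductal-like cells of EYFP negative run 3 averaged 639 per cell, 33.1 times the mean of T or NK-like cells (19.3), where an even spread of acinar RNA predicted under 3 times. The medians, 39 and 14, differed by 2.79 times, which lies under 3, so only the mean, and with it 1 cell, departs from an even spread. A doublet or clump with an acinar cell predicted that 1 cell holds most of the enzyme UMIs, and 1 cell held 95.2%. An acinar change towards duct in pancreatitis could give enzyme-bearing ductal-like cells, but with 95.2% in 1 cell these data cannot speak to it.

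Other splits of the 6 libraries into 3 and 3 tell how far the EYFP calls stand out. Of 10 splits, the real one included, 10 called at least as many genes as the real split in acinar-like cells (0 genes; highest other 327, for EYFP negative runs 1 and 2 with EYFP positive run 1), 4 in ductal-like (6; highest other 9), 5 in endothelial-like (5; highest other 45), 10 in B or plasma-like (0; highest other 30) and 5 in T or NK-like cells (2; highest other 17). If run numbers pair the libraries, which was not settled, the fair comparison is with the other splits that part all 3 pairs. Of those the highest called 0, 0, 4, 0 and 1 genes. Splits that call several times the real count point to a structure of the samples. Each of them parts 1 of the 3 pairs, but others that do so call 0 genes. The split with 327 genes holds both run 3 libraries on 1 side, where the condition term takes them up. It thus set EYFP positive run 2, with 31 of 36 cells in cluster 20, against the other homeostasis libraries. The endothelial-like splits with 45 genes set run 1 against run 2. What produced the calls was not tested. The 10 splits are too few for a share under 0.05.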
